A study of Homo sapiens with 20 samples.

How the data were processed

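Total RNA of MII cells (MCF10-T1k, a RAS-transformed human mammary epithelial line) was measured on Affymetrix HG-U133 Plus 2.0 arrays, 1 array per sample, per the labels and the deposited probe table. Per the labels, cells were transfected with siRNA by lipofection, left in normal culture and harvested, and biotin-labelled cRNA was hybridised. The labels give 5 groups of 4 biological replicates (A to D): control siRNA against GFP, siAPC, siAPC/siTAZ, siRNA against beta-catenin (sibcat) and sibcat/siTAZ. The siRNA sequences, the time between transfection and harvest, scan dates and the genome build of the probe annotation are not given in the sources used here. The values deposited by the authors are log2 signals from RMA (background correction, quantile normalization and probe set summary), per the submitters' processing notes for RMA and from the range of the values for the log2 scale. The software version of RMA is not given in the sources used here.

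The table held 54675 probe sets on 20 arrays, written with 2 decimals, and all of its columns were used. Array medians lay between 5.07 and 5.11, no pair of arrays had identical values, and each array correlated with its own group at 0.996 or more. Of the probe sets, 41097 carried 1 gene symbol in the deposited annotation, 1801 carried several and 11777 were not named here. After 56 control probe sets were left out, the 13522 without a single symbol were tested apart. Of those with 1 symbol, 41043 matched a current human gene name. For the 10523 genes with more than 1 probe set, the probe set with the highest mean over the 20 arrays was used, and 9252 genes had only 1, which gave 19775 genes tested. No filter on low values was applied. Signals of probe sets with near-identical targets in gene families may come from several members.

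Differences were tested with limma 3.58.1 in R 4.3.3. A group-means model was fitted to all 20 arrays (15 residual degrees of freedom), followed by empirical Bayes moderation (prior degrees of freedom 3.39), two-sided, with Benjamini-Hochberg adjustment over the 19775 genes in each comparison. A gene was called changed at an adjusted p under 0.05. The median residual SD per gene was 0.108 on the log2 scale, and the smallest called change after siAPC was 0.08. The comparisons were siAPC and sibcat against control, each combined depletion against its single depletion and against control, siAPC against sibcat, and the difference between the TAZ siRNA effects in the siAPC and sibcat backgrounds. The fit was tested on simulated data with 50 changed genes of each size among 19775, and it recovered 42%, 94%, 100% and 100% of changes of 0.25, 0.5, 1 and 2 on the log2 scale, with 8 false calls among 176. The simulation changed far fewer genes than were called in the data and used independent noise. These rates therefore do not carry over to the real comparisons.

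The model, the threshold, the choice of probe set, the gene lists, the named-gene rule and all alternatives were fixed before the data were examined. The 27 lists held 533 entries, 492 of them measured: YAP/TAZ-TEAD targets, beta-catenin/TCF targets, Hippo pathway components, Wnt receptors and destruction complex, siRNA targets, epithelial identity, mesenchymal genes, adherens junction, desmosome and tight junction, basal/myoepithelial markers, luminal markers, squamous differentiation, extracellular matrix and integrins, actin cytoskeleton and SRF targets, TGF-beta/SMAD targets, mitosis, S phase and DNA replication, p53 targets, interferon response, NF-kB and inflammatory cytokines, hypoxia and glycolysis, unfolded protein and amino acid stress, cholesterol biosynthesis, oxidative phosphorylation, fibroblast, endothelial and leukocyte markers. Lists were tested with limma camera at its preset correlation of 0.01 between genes, adjusted over the 27 lists of a comparison, and again with an estimated correlation. Each count of list members was given over all genes and adjusted over the list alone.

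Named genes were the siRNA targets, the reporters CCN2, CCN1, ANKRD1 and AXIN2, and in each main comparison the 10 largest rises and 10 largest falls among called genes whose groups of 4 arrays did not overlap. Up to 4 members with the smallest adjusted p stand for each list. The 5 largest differences in each direction stand for the comparisons between backgrounds, and the 10 largest rises of a single depletion stand for the genes that TAZ siRNA lowered. Genes known only from probe sets with several or no symbols were not named.

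Counts of genes shared by comparisons that use the same arrays were set beside the count for independent lists, beside 20 simulations of unchanged arrays that share those arrays, and beside the counts with the 4 shared arrays divided, 2 for each comparison, over the 6 choices. The replicate letters did not pair the arrays: the correlation of same-letter residuals between groups had a median of 0.027, and 7 of 20 arrays had their best match under their own letter. The main comparisons were therefore not paired. RNA quality was read as the 3' minus 5' signal of ACTB and GAPDH probe sets, compared with two-sided exact permutation tests, whose smallest p for 4 against 4 arrays is 0.0286.

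Each result was recomputed with the replicate letter as a block, the genes of lowest mean signal dropped (a milder filter, and a stricter one that drops 50% of the genes), the mean of all probe sets of a gene, every probe set tested on its own, arrays centred on their medians, quantile normalization of the deposited values, a trended and robust variance, array weights, only the groups compared, a minimum fold change of 1.5, and each array left out in turn. Other splits of the arrays were fitted as a test of chance, 35 for 8 arrays and 100 for the larger designs.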

Results

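RNA was measured on 20 arrays from MII cells (MCF10-T1k), a RAS-transformed human mammary epithelial line. The cells had received siRNA against GFP (control), APC, APC and TAZ, beta-catenin, or beta-catenin and TAZ, with 4 biological replicates in each of the 5 groups. APC is a scaffold of the complex that marks beta-catenin (gene CTNNB1) for degradation, and TAZ (gene WWTR1) is a transcriptional coactivator that acts with TEAD factors and is restrained by the Hippo pathway. The series title places TAZ as a mediator of Wnt signalling, so the comparisons ask which genes changed when APC or beta-catenin was depleted and what adding TAZ siRNA did to them. Array medians lay between 5.07 and 5.11 on the log2 scale, and 19775 genes were tested. The number of arrays limits the precision, and the standard errors (SE) of the log2 changes of the genes named by the largest changes lay between 0.04 and 0.17. The labels call the replicates biological without saying whether they came from separate cultures or transfections, so the p-values measure only the spread between these samples.

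Each siRNA lowered its target, and the depth of the knockdown differed between the groups. APC fell from 8.22 ± 0.06 (log2 signal, SD, n = 4) in the control to 7.34 ± 0.06 in siAPC cells, a change of -0.88 ± 0.05 (SE, limma adjusted p = 4.4e-11). CTNNB1 fell by 1.33 ± 0.05 in sibcat cells (adjusted p = 3.6e-14), from 11.94 to 10.60. WWTR1 fell by 2.67 ± 0.05 when TAZ siRNA was added to siAPC (adjusted p = 2.8e-18) and changed by -2.21 ± 0.05 when it was added to sibcat (adjusted p = 8.9e-17). WWTR1 had already fallen by 0.41 in siAPC cells and by 0.43 in sibcat cells. The other targets did not stay level when TAZ siRNA was added. CTNNB1 fell by a further 1.41 ± 0.05 in sibcat/siTAZ cells (adjusted p = 1.5e-14), to 9.20 ± 0.06, and APC fell by a further 0.46 ± 0.05 in siAPC/siTAZ cells (adjusted p = 5.1e-07), although the mean over all APC probe sets changed by -0.10 with adjusted p = 0.171. One CTNNB1 probe set did not fall in sibcat cells (0.15 ± 0.06, adjusted p = 0.0718) and rose by 0.21 when TAZ siRNA was added (adjusted p = 0.0152), and the other 2 fell. The comparison of sibcat/siTAZ with sibcat therefore carries a deeper CTNNB1 knockdown as well as the loss of TAZ, while for APC this rests on the choice of probe set, and no group received TAZ siRNA alone.

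**Figure D1:**
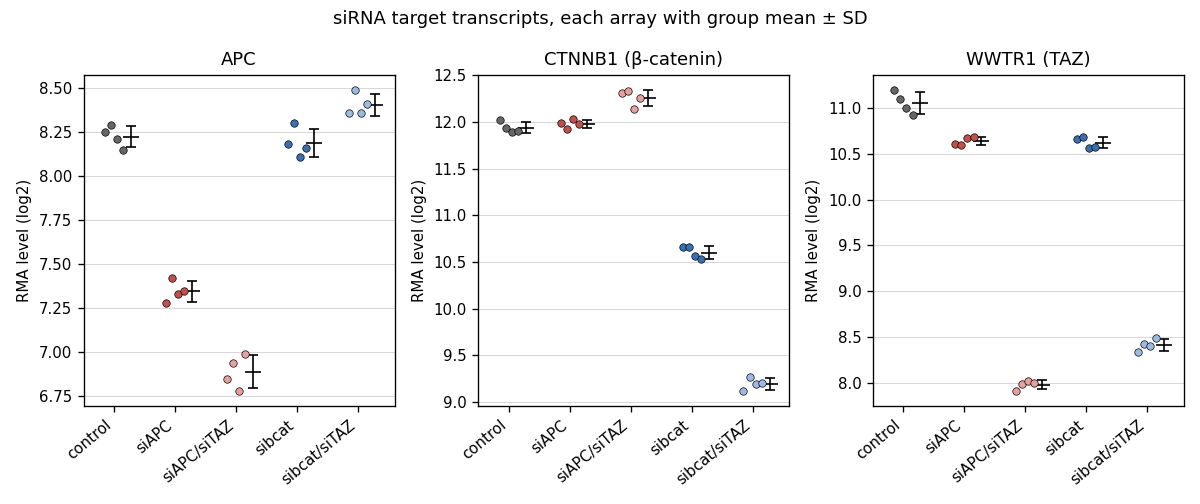
Log2 signal of APC, CTNNB1 and WWTR1 on each of the 20 arrays (points), by siRNA group on the horizontal axis, with the mean and SD of the 4 arrays of each group. WWTR1 lies at 7.98 in siAPC/siTAZ and 8.41 in sibcat/siTAZ cells against 11.06 in the control, and CTNNB1 lies at 10.60 in sibcat and 9.20 in sibcat/siTAZ cells.

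After APC depletion, targets of both beta-catenin/TCF and YAP/TAZ-TEAD rose while epithelial genes fell. AXIN2, a feedback inhibitor of Wnt signalling and a standard beta-catenin target, rose by 5.30 ± 0.08 (log2, SE, adjusted p = 4.1e-20), from 4.79 ± 0.12 to 10.10 ± 0.03 (SD, n = 4). The TEAD targets rose with it: ANKRD1 by 5.65 ± 0.10 (adjusted p = 5.3e-19), CCN1 by 3.37 ± 0.06 and CCN2 by 3.27 ± 0.17. Among the other largest rises were the secreted protease ADAMTS1 (46.0-fold), the scavenger receptor OLR1 (36.2-fold), the transporter ABCA8 (30.5-fold), the oxytocin receptor OXTR (25.9-fold), the ligand BMP4 (24.9-fold), LYPD6 (21.9-fold), the hyaluronan synthase HAS2 (21.9-fold) and EDIL3 (21.0-fold). The control signals of ANKRD1 (3.08), ABCA8 (2.84), OLR1 (3.68) and LYPD6 (3.69) lay well below the array medians, where background compresses a fold, so their folds are lower limits and their rank is uncertain. The largest falls were in the tight-junction gene CLDN8 (-5.02 ± 0.13), the secretoglobin SCGB1A1 (-4.87), the amino acid transporter SLC6A14 (-4.30), ART3 (-3.77), ARL14 (-3.70), SERPINA3 (-3.60), GABRP (-3.29) and the cyclooxygenase PTGS1 (-3.21). SERPINB3 and SERPINB4 changed by -3.68 and -3.49, and their sequences are so alike that the probe sets may not separate them. In all, 7913 genes changed, 4218 higher and 3695 lower, of which 708 changed at least 2-fold (368 higher, 340 lower).

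The fixed gene lists showed the same split after APC depletion, and a call holds with an estimated correlation between genes wherever no other value is given. Of 21 YAP/TAZ-TEAD targets measured, 18 rose, 1 fell and 2 were not called (list mean 1.37, limma camera adjusted p = 2.2e-13), with IGFBP3 at 2.41 and CRIM1 at 1.66. Of 26 beta-catenin/TCF targets, 16 rose and 5 fell (mean 0.92, adjusted p = 0.00021), with LEF1 at 2.96 and MSX2 at 2.22. The 5 that fell were SOX9 (-0.87), ID2 (-0.79), EPHB3 (-0.775), MYC (-0.47) and CD44 (-0.325). The call for beta-catenin/TCF targets was lost when every probe set was tested on its own (adjusted p = 0.149). Of 15 epithelial identity genes, 14 fell and none rose (mean -0.81, adjusted p = 2.1e-10), with the transcription factor ELF3 at -2.25, the splicing factor ESRP1 at -1.23 and CDS1 at -1.08. The unfolded protein and amino acid stress list rose (13 higher, 2 lower, mean 0.50, adjusted p = 6.0e-05), led by asparagine synthetase ASNS at 2.33 and SLC7A11 at 1.39. Hippo pathway components rose (12 higher, 3 lower, mean 0.29, adjusted p = 0.00383), with NF2 at 1.21 and WWC1 at 1.13 while YAP1 fell by 0.58. Mesenchymal genes rose (11 higher, 4 lower, mean 0.30, adjusted p = 0.00383), with ZEB1 at 1.51 and CDH2 at 0.95 and S100A4 at -1.13. Cholesterol biosynthesis rose slightly (10 higher, 2 lower, mean 0.20, adjusted p = 0.0192), with FDPS at 0.74, a call lost when genes of low signal were dropped (adjusted p = 0.0502 with the milder and 0.168 with the stricter filter).

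Several lists fell after APC depletion. Hypoxia and glycolysis genes were lower (2 higher, 13 lower, mean -0.23, adjusted p = 0.00021), with PDK1 at -0.67 and KDM3A at -0.63, although ADM rose by 1.31. S phase genes were lower (3 higher, 16 lower, mean -0.20, adjusted p = 0.00214), with MCM6 at -0.82 and UHRF1 at -0.57. Desmosome and tight junction genes were lower (3 higher, 9 lower, mean -0.26, adjusted p = 0.00383), with the claudin CLDN1 at -0.83. Squamous differentiation genes were lower (3 higher, 10 lower, mean -0.49, adjusted p = 0.0127), with S100A8 at -2.73, S100A9 at -2.18 and IVL at -1.32. Basal and myoepithelial markers were lower (2 higher, 7 lower, mean -0.43, adjusted p = 0.00477, but adjusted p = 0.119 with an estimated correlation), with LAMB3 at -1.02. Interferon response genes were lower (3 higher, 13 lower, mean -0.32, adjusted p = 0.00383, but adjusted p = 0.154 with an estimated correlation), with IFIT2 at -1.76 and OAS1 at -1.36 against IFI44 at 1.20. The p53 targets were higher (9 higher, 4 lower, mean 0.22, adjusted p = 0.0364, but adjusted p = 0.203 with an estimated correlation), with FAS and SESN2 at 0.83 each. Adjusted over the list alone, the counts in these 14 lists were the same except for Hippo components (13 higher, 4 lower), mesenchymal genes (12 higher, 4 lower), the stress list (14 higher, 2 lower), cholesterol biosynthesis (10 higher, 3 lower) and desmosome genes (3 higher, 10 lower).

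The other 13 lists were not called after APC depletion. The mitosis list had 7 genes higher and 14 lower (mean -0.07, adjusted p = 0.144), and the list of NF-kB targets and cytokines had 6 higher and 4 lower (adjusted p = 0.592), with CXCL1 at 2.54 and CXCL8 at 2.48 against IL6 at -1.57. Leukocyte markers had 5 genes lower, CD14 among them at -2.70, and none higher (adjusted p = 0.0687). The adjusted p was 0.193 for extracellular matrix and integrin genes, 0.372 for actin and SRF targets, 0.466 for endothelial markers, 0.495 for both fibroblast markers and oxidative phosphorylation, 0.682 for Wnt receptors and destruction complex genes, 0.789 for luminal markers, 0.887 for adherens junction genes, 0.938 for TGF-beta/SMAD targets and 0.0687 for the 3 siRNA targets. As a measure of RNA quality, the 3' minus 5' signal of ACTB was 0.26 lower in siAPC cells than in the control (log2, two-sided exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give, adjusted p = 0.0381).

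Depletion of beta-catenin raised many of the YAP/TAZ-TEAD targets that APC depletion raised, without AXIN2, and it raised mitosis and interferon genes. ANKRD1 rose by 5.10 ± 0.10 (log2, SE, adjusted p = 4.3e-18), from 3.08 ± 0.21 to 8.18 ± 0.12 (SD, n = 4), CCN1 by 2.94 ± 0.06 and CCN2 by 2.80 ± 0.17, while AXIN2 fell by 0.51 ± 0.08 (adjusted p = 2.3e-05). The other largest rises were in ADAMTS1 (30.3-fold), ABCA8 (20.4-fold), OXTR (18.3-fold), LYPD6 (16.4-fold), OLR1 (15.3-fold), EDIL3 (14.6-fold), the proteoglycan SRGN (14.5-fold), the bicarbonate transporter SLC4A4 (13.1-fold) and ZNF385B (12.1-fold). The limit of low control signals holds here too, also for SLC4A4 (2.65) and ZNF385B (4.26). For SRGN, 1 of 3 probe sets was called the opposite way. The largest falls were in SLC6A14 (-5.37 ± 0.13), GABRP (-4.95), the keratins KRT13 and KRT23 (-4.88 and -4.76), SCGB1A1 (-4.75), the adhesion genes CEACAM6 and CEACAM1 (-4.53 and -3.25), CLDN8 (-4.25), BLNK (-3.52) and VTCN1 (-3.40). In all, 7344 genes changed, 4233 higher and 3111 lower, and 480 changed at least 2-fold (197 higher, 283 lower).

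In the lists, YAP/TAZ-TEAD targets rose after beta-catenin depletion (16 higher, 1 lower, mean 1.13, camera adjusted p = 4.3e-13), with IGFBP3 at 2.14 and CCDC80 at 1.96. Mitosis genes rose nearly throughout (26 higher, 0 lower of 28, mean 0.55, adjusted p = 3.9e-17), with the kinetochore motor CENPE at 1.07, BIRC5 at 0.81 and BUB1 at 0.64. S phase genes rose (21 higher, 0 lower, mean 0.26, adjusted p = 1.0e-06), with RRM2 at 0.86. Interferon response genes rose (22 higher, 1 lower, mean 0.97, adjusted p = 7.5e-13), with IFIT1 at 2.22, ISG15 at 2.13, IFI44 at 2.09 and IFI44L at 2.02. The stress list rose (13 higher, 2 lower, mean 0.41, adjusted p = 3.2e-05), with ASNS at 1.98 and PSAT1 at 0.94, and cholesterol biosynthesis rose (9 higher, 0 lower, mean 0.19, adjusted p = 0.00852), with INSIG1 at 0.70, the cholesterol call being lost with the stricter filter on low signals (adjusted p = 0.126). Mesenchymal genes rose (8 higher, 3 lower, mean 0.18, adjusted p = 0.0303, but adjusted p = 0.0964 with an estimated correlation), with ZEB1 at 1.06 and TWIST1 at 0.77.

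Beta-catenin/TCF targets fell on balance after beta-catenin depletion (2 higher, 11 lower, 13 not called, mean -0.20, adjusted p = 0.00852), with ID2 at -1.07 and SOX9 at -0.73, although BMP4 rose by 2.39 and DKK1 by 0.63. ID2 and SOX9 had also fallen after siAPC (-0.79 and -0.87), so their falls do not separate the 2 depletions. All 15 epithelial identity genes fell (mean -0.89, adjusted p = 2.7e-14), with RAB25 at -1.93, ELF3 at -1.75, GRHL1 at -1.28 and ESRP1 at -1.14. Desmosome and tight junction genes fell (0 higher, 13 lower, mean -0.50, adjusted p = 4.8e-09), with CLDN1 at -1.19 and the desmoglein DSG3 at -1.16. Squamous genes fell (0 higher, 13 lower, mean -0.84, adjusted p = 8.3e-08), with SPRR1B at -2.44 and IVL at -1.69, and basal markers fell (0 higher, 8 lower, mean -0.59, adjusted p = 1.0e-06), with LAMB3 at -0.76 and KRT15 at -0.73. Hypoxia genes fell (1 higher, 14 lower, mean -0.30, adjusted p = 1.0e-06), with NDRG1 at -0.80 and VEGFA at -0.72, and NF-kB targets fell (2 higher, 11 lower, mean -0.27, adjusted p = 0.00167), with PTGS2 at -2.25 and IL1B at -0.78 against IL6 at 1.21. The 3 siRNA targets, taken as a list, had 2 genes lower (adjusted p = 0.00996, but adjusted p = 0.111 with an estimated correlation). Adjusted over the list alone, the counts differed for YAP/TAZ-TEAD targets (18 higher, 1 lower), S phase genes (22 higher, 0 lower), the stress list (14 higher, 2 lower), cholesterol biosynthesis (10 higher, 0 lower), mesenchymal genes (10 higher, 3 lower), desmosome genes (1 higher, 13 lower), squamous genes (0 higher, 14 lower) and hypoxia genes (1 higher, 15 lower).

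The lists without a call after beta-catenin depletion had adjusted p = 0.347 (Hippo components), 0.332 (extracellular matrix), 0.811 (TGF-beta/SMAD), 0.903 (p53 and endothelial), 0.184 (luminal and leukocyte), 0.112 (actin and SRF), 0.110 (adherens junction), 0.762 (Wnt receptors), 0.781 (oxidative phosphorylation) and 0.529 (fibroblast). The ACTB 3' minus 5' signal differed from the control by -0.02 (exact permutation p = 0.714).

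Both single depletions changed 4414 genes in the same direction, 2535 higher and 1879 lower, against 1484 for independent lists. Simulated unchanged arrays gave a mean of 0.05, but such arrays hold almost no called genes, so this low count was certain beforehand. A further 813 genes changed in opposite directions. Since both comparisons use the control arrays, these were also divided, 2 arrays for each comparison. The median over the 6 choices was then 3563 genes (3495 to 3610), against at most 1159 for independent lists. Dividing the arrays removes only the noise of single control arrays. A trait common to all 4 control arrays would shift both comparisons alike, and it cannot be told apart from a shared effect of the depletions. Across genes, which are not independent replicates, the log2 changes had r = 0.71 and rho = 0.55 (simulated r = 0.50), with a covariance of 0.121 against 0.0036 in the simulation. Of the 368 genes raised at least 2-fold by siAPC, 298 were called higher in sibcat cells, 27 lower and 43 neither. In the direct comparison, 6690 genes differed between siAPC and sibcat cells (3223 higher in siAPC, 3467 lower). AXIN2 was 5.81 ± 0.08 higher in siAPC (SE, adjusted p = 4.6e-20), followed by IGFL2 (4.32), the gap junction gene GJA1 (4.12), TDO2 (3.83) and the Wnt antagonist DKK2 (3.62). IFI6 (-2.80), IL6 (-2.78), ASB9 (-2.71), IQGAP2 (-2.69) and ARL14 (-2.60) were lower. The sibcat signals of DKK2 (2.52), TDO2 (3.47) and AXIN2 (4.29) lay below the array medians, as did the siAPC signals of ARL14 (4.10) and ASB9 (4.93). Background may compress these differences, so their rank is uncertain. Beta-catenin/TCF targets were higher in siAPC (list mean 1.12, adjusted p = 8.3e-09), and the interferon (-1.29, adjusted p = 3.6e-22) and mitosis (-0.62, adjusted p = 1.8e-23) lists were lower.

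Adding TAZ siRNA to APC depletion lowered the TEAD targets, more of them to below the control than stayed above it, and left the beta-catenin targets high. CCN2 fell by 6.76 ± 0.17 (log2, SE, adjusted p = 6.7e-17), ANKRD1 by 5.64 ± 0.10 (adjusted p = 5.6e-19) and CCN1 by 3.90 ± 0.06. CCN2 ended at 4.27 and CCN1 at 8.18, below their control signals of 7.76 and 8.71. ANKRD1 ended at 3.09 ± 0.19 against 3.08 ± 0.21 in the control (SD, n = 4), a control signal too low to show a fall below it. AXIN2 rose by a further 0.86 ± 0.08 (adjusted p = 1.3e-08). Other large falls were in SRGN (-6.60), OXTR (-5.42), PRR16 (-4.72), AOX1 (-4.66), CCBE1 (-4.49), LYPD6 (-4.37), the integrin ITGB2 (-4.34) and PSG9 (-4.23), a member of a gene family so alike that its probe set may read several members. End signals such as those of LYPD6 (3.785), PSG9 (3.97), ITGB2 (4.05) and CCN2 lay below the array medians. Background may compress such falls, so their rank is uncertain. The fibrillar collagen genes COL3A1 and COL1A1 rose by 4.78 ± 0.13 and 2.68 ± 0.06, with 1 of 5 COL1A1 probe sets called the opposite way. The collagenase MMP1 (3.56), the sulfotransferase SULT1E1 (3.50), FABP4 (3.33), the cytokines IL33 (3.01) and TNFSF10 (2.81), the Wnt receptor FZD10 (2.96), ARL14 (2.76) and DKK2 (2.91, with 1 of 2 probe sets called the opposite way) rose too. In all, 8607 genes changed, 4102 higher and 4505 lower, and 863 changed at least 2-fold (393 higher, 470 lower).

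Among the lists, YAP/TAZ-TEAD targets fell when TAZ siRNA was added to siAPC (0 higher, 19 lower of 21, mean -1.88, camera adjusted p = 2.3e-17), with AMOTL2 at -2.87 and CRIM1 at -2.77. Beta-catenin/TCF targets rose (19 higher, 2 lower, mean 0.54, adjusted p = 1.8e-06), with CCN4 at 2.10, ID2 at 1.72 and LEF1 at 1.23, while DKK1 fell by 2.30. Hypoxia and glycolysis genes fell (1 higher, 18 lower, mean -1.25, adjusted p = 3.7e-14), with the peptide hormone gene ADM at -3.56, ANKRD37 at -2.27, hexokinase HK2 at -1.70 and NDRG1 at -1.57. Cholesterol biosynthesis fell (0 higher, 13 lower, mean -0.73, adjusted p = 2.8e-08), with INSIG1 at -1.98 and SQLE at -1.57. Mitosis genes fell (0 higher, 27 lower, mean -0.63, adjusted p = 3.7e-14), with NUF2 at -1.81, CDC20 at -1.40 and cyclin B1 (CCNB1) at -0.95. S phase genes fell (0 higher, 23 lower, mean -0.64, adjusted p = 1.8e-12), with CCNE2 at -1.55, MCM6 at -1.50 and GINS2 at -1.36. The stress list fell (1 higher, 15 lower, mean -0.64, adjusted p = 7.2e-07), with ASNS at -3.26 and PHGDH at -1.33. Mesenchymal genes rose (14 higher, 3 lower, mean 0.58, adjusted p = 2.8e-05), with SPARC at 2.38, TAGLN at 1.78 and POSTN at 1.75, and NF-kB targets rose (11 higher, 3 lower, mean 0.27, adjusted p = 0.00531), with CXCL2 at 1.40.

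A further 5 lists were called only with the preset correlation when TAZ siRNA was added to siAPC. TGF-beta/SMAD targets had 10 genes higher and 1 lower (mean 0.52, adjusted p = 7.8e-05, but adjusted p = 0.0952 with an estimated correlation), with ID3 at 2.02 and ID1 at 1.78. The p53 targets had 10 higher and 3 lower (adjusted p = 0.00363, but adjusted p = 0.0952 with an estimated correlation), with SESN1 at 1.19, and fibroblast markers had 6 higher and 1 lower (adjusted p = 0.0177, but adjusted p = 0.114 with an estimated correlation), with COL6A1 at 1.42 and DCN at 1.18. Luminal markers had 2 higher and 6 lower (adjusted p = 0.0189, but adjusted p = 0.210 with an estimated correlation), with the keratins KRT7 at -1.53, KRT8 at -1.47 and KRT18 at -1.35. The extracellular matrix list had 18 higher and 7 lower (adjusted p = 0.0345, but adjusted p = 0.256 with an estimated correlation), with MMP1 at 3.56 against TIMP2 at -3.35, COL8A1 at -3.00 and LOXL2 at -1.76. Adjusted over the list alone, the counts of these 14 lists were the same except for YAP/TAZ-TEAD targets (20 lower), S phase genes (24 lower), the stress list (1 higher, 16 lower) and NF-kB targets (12 higher, 3 lower). The lists without a call had adjusted p = 0.186 (interferon, 9 higher and 4 lower), 0.588 (epithelial identity, 5 higher and 6 lower), 0.680 (Hippo components and squamous genes), 0.561 (desmosome), 0.923 (basal), 0.553 (actin and SRF), 0.246 (adherens junction), 0.456 (Wnt receptors), 0.633 (oxidative phosphorylation), 0.722 (endothelial), 0.623 (leukocyte) and 0.174 (siRNA targets). The ACTB 3' minus 5' signal was 0.42 higher in siAPC/siTAZ than in siAPC cells (exact permutation p = 0.0286, adjusted p = 0.0381).

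**Figure D2:**
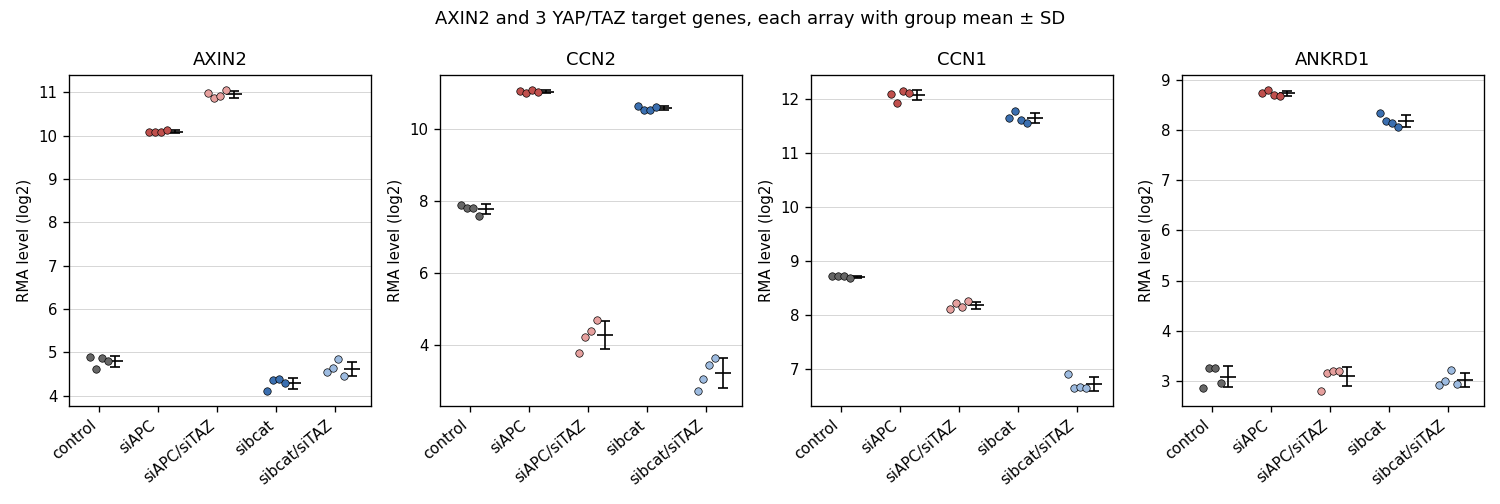
Log2 signal of AXIN2, CCN2, CCN1 and ANKRD1 on each of the 20 arrays (points), by siRNA group, with the mean and SD of the 4 arrays of each group. AXIN2 is high only in the groups with APC siRNA (10.10 and 10.96), whereas ANKRD1 is high only in the groups without TAZ siRNA in which APC (8.73) or beta-catenin (8.18) was depleted.

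When TAZ siRNA was added to beta-catenin depletion, TEAD targets fell as they did in the siAPC background, while interferon and mitosis genes rose further. CCN2 fell by 7.35 ± 0.17 (log2, SE, adjusted p = 3.4e-17), ANKRD1 by 5.16 ± 0.10 (adjusted p = 3.2e-18) and CCN1 by 4.94 ± 0.06 (adjusted p = 7.7e-21). Other large falls were in CCBE1 (-4.47), OLR1 (-4.33), ABCA8 (-4.23), LYPD6B (-3.92), TMEM178B (-3.92), SRGN (-3.89) and RGCC (-3.77). In sibcat/siTAZ cells CCN2 ended at 3.21 ± 0.41 (SD, n = 4), ANKRD1 at 3.02, OLR1 at 3.30, ABCA8 at 2.955 and RGCC at 3.48, well below the array medians. Background may compress these falls, so their sizes are lower limits and their rank is uncertain. COL3A1 rose by 3.61 ± 0.13 (adjusted p = 2.1e-14), PI15 by 3.19, SULT1E1 by 3.08, PTPRZ1 by 2.89, MMP1 by 2.58, TNFAIP6 by 2.52, TMEM100 by 2.48, ENPP2 by 2.32, FABP4 by 2.30 and F2RL2 by 2.29. AXIN2 rose by 0.33 ± 0.08 (adjusted p = 0.00205), but the mean over its probe sets missed the threshold (0.11, adjusted p = 0.181). In all, 6264 genes changed, 3555 higher and 2709 lower, and 456 changed at least 2-fold (160 higher, 296 lower).

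YAP/TAZ-TEAD targets fell when TAZ siRNA was added to sibcat (0 higher, 19 lower, mean -1.95, camera adjusted p = 2.5e-26), with AMOTL2 at -3.52, CRIM1 at -3.42 and TGFB2 at -2.88. Hypoxia genes fell (0 higher, 18 lower, mean -0.88, adjusted p = 1.5e-18), with ADM at -3.00, EGLN3 at -2.40 and NDRG1 at -1.54. Cholesterol biosynthesis fell (1 higher, 12 lower, mean -0.43, adjusted p = 1.6e-08), with SQLE at -0.96 and LSS at -0.85, and the stress list fell (2 higher, 13 lower, mean -0.47, adjusted p = 3.5e-07), with ASNS at -2.03 and VLDLR at -1.59. Luminal markers fell (0 higher, 8 lower, mean -0.41, adjusted p = 1.4e-05), with KRT7 at -1.68 and KRT18 at -0.82. Hippo components fell (5 higher, 12 lower, mean -0.23, adjusted p = 0.00637), with WWC1 at -1.03 and NF2 at -0.89. Interferon genes rose (23 higher, 0 lower, mean 0.93, adjusted p = 3.7e-19), with IFI44L at 1.40, IFI44 at 1.16, ISG15 at 1.03 and RIGI at 0.94. Mitosis genes rose (23 higher, 0 lower, mean 0.27, adjusted p = 2.1e-09), with CENPE at 0.66 and NDC80 at 0.50. NF-kB targets rose (10 higher, 3 lower, mean 0.34, adjusted p = 0.00094), with CXCL1 at 1.70 and CXCL8 at 1.42, and mesenchymal genes rose (10 higher, 3 lower, mean 0.35, adjusted p = 0.00263), with SPARC at 1.72 and POSTN at 1.55.

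The 3 siRNA targets had 1 gene higher and 2 lower when TAZ siRNA was added to sibcat (adjusted p = 0.00822, but adjusted p = 0.126 with an estimated correlation). Beta-catenin/TCF targets were not called (8 higher, 5 lower, mean -0.15 and median 0.08, adjusted p = 0.864), with ID2 at 1.11 against BMP4 at -2.64, DKK1 at -2.29 and CCND1 at -1.97. Adjusted over the list alone, the counts differed for cholesterol biosynthesis (1 higher, 13 lower), mesenchymal genes (11 higher, 3 lower), NF-kB targets (12 higher, 3 lower) and beta-catenin/TCF targets (10 higher, 5 lower). The other lists without a call had adjusted p = 0.221 (S phase), 0.0502 (extracellular matrix), 0.0825 (TGF-beta/SMAD, epithelial identity, and actin and SRF), 0.129 (fibroblast), 0.163 (desmosome), 0.685 (basal), 0.960 (squamous), 0.980 (p53), 0.104 (adherens junction), 0.923 (Wnt receptors), 0.329 (oxidative phosphorylation), 0.864 (endothelial) and 0.882 (leukocyte). List mean, median and test direction differed in sign only in lists without a call: actin and SRF, luminal, TGF-beta/SMAD and Wnt receptor lists after siAPC, endothelial and fibroblast lists after sibcat, Hippo, oxidative phosphorylation and squamous lists for TAZ siRNA in siAPC, and beta-catenin/TCF, fibroblast, p53, squamous and Wnt receptor lists for TAZ siRNA in sibcat. The ACTB 3' minus 5' signal was 0.23 higher in sibcat/siTAZ than in sibcat cells (exact permutation p = 0.0286, adjusted p = 0.0381).

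**Figure D3:**
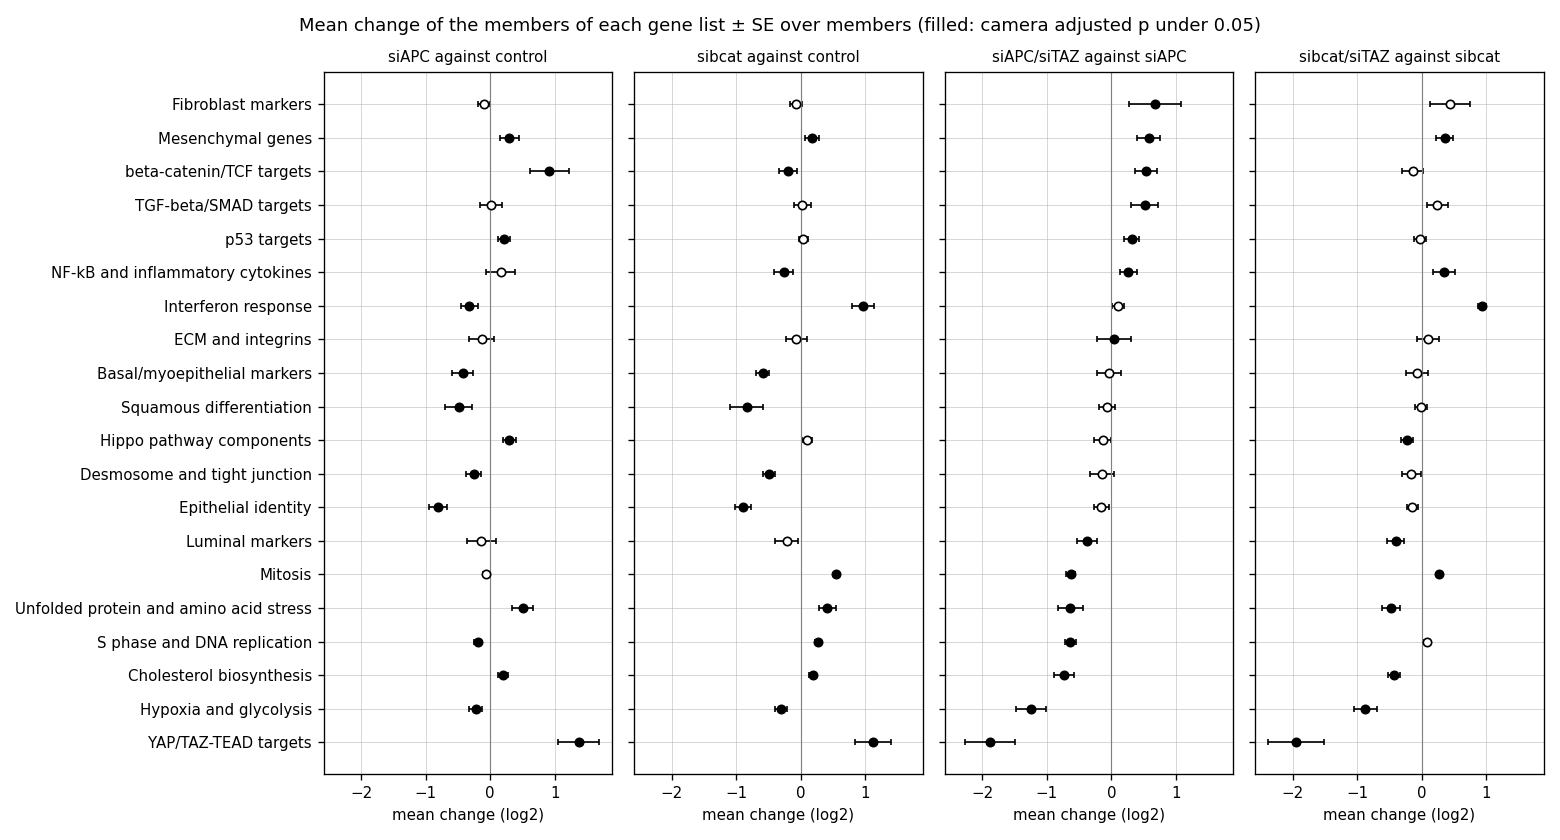
Mean log2 change of each gene list (points) with its SE over the members, in the 4 main comparisons, with filled points where the camera adjusted p was below 0.05. The YAP/TAZ-TEAD list lies at 1.37 and 1.13 in the single depletions and at -1.88 and -1.95 when TAZ siRNA was added.

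Genes raised at least 2-fold by a single depletion were often lowered by the added TAZ siRNA. Of the 368 genes raised at least 2-fold by siAPC, 235 (63.9%) fell when TAZ siRNA was added, 105 rose further and 28 were not called. Of the 197 raised at least 2-fold by sibcat, 161 (81.7%) fell, 31 rose further and 5 were not called. In the siAPC background the genes with the largest rises that fell were ANKRD1 (-5.64), ADAMTS1 (-3.73), OLR1 (-1.29), ABCA8 (-3.96), OXTR (-5.42), LYPD6 (-4.37), EDIL3 (-1.53), SRGN (-6.60), SLC4A4 (-4.16) and ZNF385B (-4.09). The same 10 genes led in the sibcat background: ANKRD1 (-5.16), ADAMTS1 (-3.57), OLR1 (-4.33), ABCA8 (-4.23), OXTR (-3.44), LYPD6 (-3.65), EDIL3 (-3.13), SRGN (-3.89), SLC4A4 (-3.62) and ZNF385B (-3.26). By contrast AXIN2, BMP4 and HAS2, also among the largest rises after siAPC, rose by a further 0.86, 0.59 and 1.30. Genes lowered at least 2-fold turned back in 234 of 340 cases (68.8%) after siAPC and in 120 of 283 (42.4%) after sibcat. These counts take any called opposite change, however small, in genes picked on the same single-depletion arrays. For the lowered genes, the median change with TAZ siRNA was 0.59 after siAPC and 0.12 after sibcat, from -1.42 and -1.415. For the raised genes, it was -0.78 and -1.42, from 1.51 and 1.39. Among all 19775 genes, TAZ siRNA lowered 4505 and raised 4102 in siAPC, and lowered 2709 and raised 3555 in sibcat.

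At any size, 1891 genes were raised by siAPC and lowered by added TAZ siRNA, against 961 for independent lists, and 1010 were raised by sibcat and lowered, against 580. The opposite pattern, lowered and then raised, held for 1546 genes (766 for independent lists) after siAPC and 936 (559) after sibcat. Genes that rose at both steps were also more than independent lists give, at 1154 (875) and 1354 (761). So were genes that fell at both steps, at 936 (842) and 746 (426). Of the genes raised by sibcat at any size, more therefore rose further (1354) than fell (1010). Simulated unchanged arrays gave 0 in each case, which was certain beforehand, since such arrays hold almost no called genes. The single-depletion arrays enter both steps with opposite signs, so they were divided too, 2 arrays for each step, and the medians over 6 choices were 1526 genes (1501 to 1562, at most 747 for independent lists) and 787 genes (771 to 832, at most 489). Across genes, siAPC and added-TAZ changes had r = -0.38 and rho = -0.23, where the simulation gave -0.50, and a covariance of -0.0795 against -0.0036. For sibcat these were r = -0.30, rho = -0.05 and -0.0418 against -0.0036.

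The TAZ siRNA effects in the 2 backgrounds share no arrays, and 4086 genes changed the same way in both, 2234 higher and 1852 lower, against 1355 for independent lists, with 697 in opposite directions. Across genes r was 0.72 and rho 0.49, against -0.0006 in the simulation, with a covariance of 0.122. The effect differed between backgrounds for 5480 genes, 2407 with a higher and 3073 with a lower value in the siAPC background. The difference was called lower in the siAPC background for 28 of 28 mitosis genes (mean difference -0.90, adjusted p = 2.4e-29), 24 of 27 S phase genes (mean -0.71, adjusted p = 2.4e-19) and 23 of 24 interferon genes (mean -0.82, adjusted p = 2.1e-14). Beta-catenin/TCF targets (17 higher, 0 lower, mean 0.69, adjusted p = 6.2e-11) and p53 targets (11 higher, mean 0.35, adjusted p = 6.4e-07) had higher values in the siAPC background. The YAP/TAZ-TEAD list had no called difference (7 higher, 7 lower, mean 0.07, adjusted p = 0.528). The largest single differences were BMP4 (3.23 ± 0.11, SE), ARL14 (3.08), OLR1 (3.04), IL33 (2.90) and DKK2 (2.75) upward and PRR16 (-3.38), TIMP2 (-3.23), SDC2 (-2.73), SRGN (-2.71) and DEK (-2.36) downward. In sibcat and sibcat/siTAZ cells DKK2 (2.52 and 2.68) and IL33 (2.99 and 3.10) lay well below the array medians, and OLR1 ended at 3.30. The differences of these genes and their ranks are therefore uncertain. TAZ siRNA lowered WWTR1 by 0.45 more in the siAPC background (adjusted p = 0.00012), so the backgrounds were not matched for the depth of TAZ loss.

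**Figure D4:**
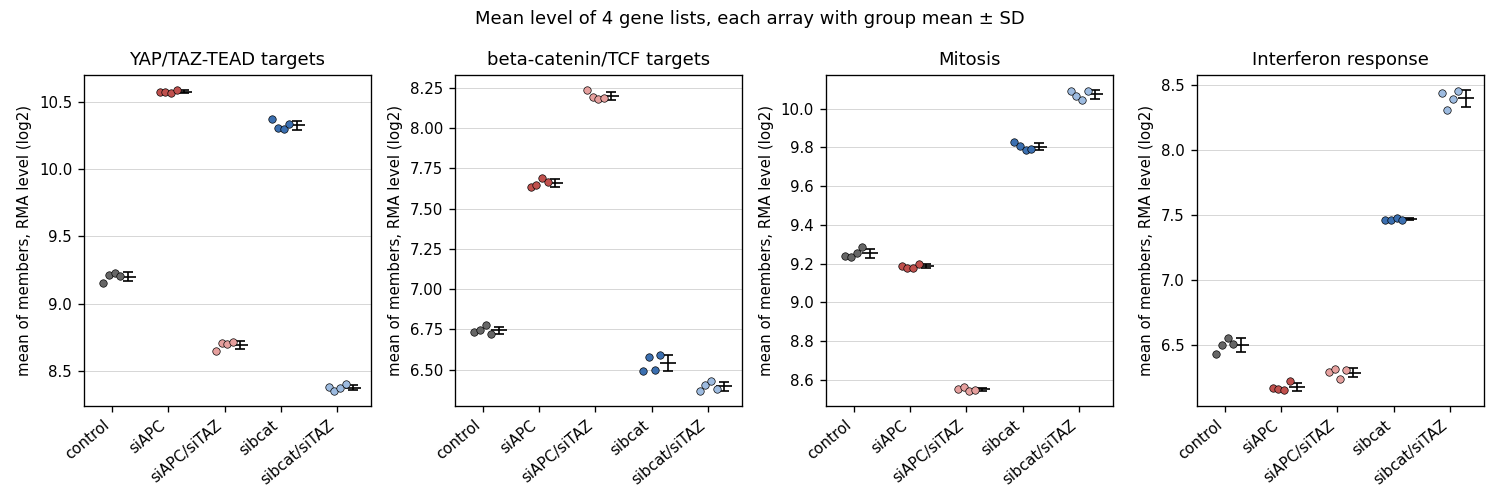
Mean log2 signal of 4 gene lists on each of the 20 arrays (points), by siRNA group, with the mean and SD of the 4 arrays of each group. The mitosis and interferon lists are highest in sibcat/siTAZ cells, and the YAP/TAZ-TEAD list is highest in the single depletions.

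Cells with both siRNAs still differed widely from the control, with epithelial identity genes low in either background. In siAPC/siTAZ cells 9338 genes differed (4542 higher, 4796 lower), and in sibcat/siTAZ cells 8887 differed (5023 higher, 3864 lower). Of the epithelial identity genes, 15 of 15 were lower in siAPC/siTAZ (mean -0.96, adjusted p = 1.9e-09) and 14 of 15 lower in sibcat/siTAZ cells (mean -1.04, adjusted p = 1.4e-11). Beta-catenin/TCF targets were high in siAPC/siTAZ (16 higher, 3 lower, mean 1.46, adjusted p = 8.0e-07) and low in sibcat/siTAZ cells (1 higher, 10 lower, mean -0.35, adjusted p = 0.00443). Hypoxia genes were lower in 19 of 19 cases in both groups (means -1.47 and -1.18, adjusted p = 3.4e-16 and 5.8e-17). YAP/TAZ-TEAD targets were lower in sibcat/siTAZ cells (5 higher, 13 lower, mean -0.82, adjusted p = 1.0e-05) and lower in siAPC/siTAZ cells only with the preset correlation (6 higher, 11 lower, mean -0.50, adjusted p = 0.0398, but adjusted p = 0.178 with an estimated correlation). Interferon genes were higher in sibcat/siTAZ cells (23 higher, mean 1.90, adjusted p = 1.4e-18) and not called in siAPC/siTAZ cells (6 higher, 11 lower, adjusted p = 0.216).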

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

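The tests of a deeper beta-catenin knockdown, of the TAZ siRNA by itself, of the beta-catenin siRNA duplex and of RNA quality by ACTB were chosen only after the results were seen. Interferon genes rose by 0.93 (list mean, log2) when TAZ siRNA was added to beta-catenin depletion, whereas with APC depletion their mean of 0.11 was not called. The difference was -0.82 ± 0.08 (SE over members, which are not independent replicates). List means of single arrays lay at 7.46 to 7.48 in sibcat and 8.30 to 8.45 in sibcat/siTAZ cells. They lay at 6.15 to 6.22 in siAPC and 6.23 to 6.31 in siAPC/siTAZ cells. These values argue against a log2 effect of the TAZ siRNA duplex equal in both backgrounds. The same difference is what flagged the list, so it is no separate test. Single members did change with TAZ siRNA in the siAPC background, IFI6 by 0.88, IFI44L by 0.82, RIGI by 0.745 and IFIT2 by -1.09. A duplex effect of unequal size stays possible and was not tested. The planned measure of RNA quality, the GAPDH 3' minus 5' signal, leaned toward that explanation without deciding it: it moved by 0.06 in the sibcat background (two-sided exact permutation p = 0.0571) and by 0.03 in the siAPC background (exact p = 0.0857), a difference of -0.03 ± 0.02 (SE). RNA quality as the whole cause is argued against by ACTB alone, which moved further in the siAPC background, where the list was not called (0.42 against 0.23, a difference of 0.19 ± 0.06, SE). A response to the beta-catenin siRNA duplex, more effective with both siRNAs, cannot be told apart from a response to the loss of beta-catenin, since the list had already risen by 0.97 ± 0.17 in sibcat cells and CTNNB1 fell further in sibcat/siTAZ cells. A biological dependence on beta-catenin may also be the cause, and the labels describe no second siRNA sequence that would test it.

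Mitosis genes fell by 0.63 with added TAZ siRNA in the siAPC background and rose by 0.27 in the sibcat background. No single array decided it, since both signs held in 20 of 20 fits that left out 1 array. The list means lay -0.61 and 0.26 from the median of all genes. On single arrays they went from 9.18 to 9.20 in siAPC to 8.54 to 8.56 in siAPC/siTAZ cells, and from 9.79 to 9.83 in sibcat to 10.05 to 10.09 in sibcat/siTAZ cells. These values argue against a scaling that moves all genes alike as the cause of the shift relative to other genes. The deposited normalization holds the median near 0, so a change common to all genes would be hidden, and the absolute direction is not decided. The unequal depth of the knockdowns stays open, and no biological explanation was tested.

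Genes raised by a single depletion and lowered by added TAZ siRNA were more than independent lists give in 6 of 6 divisions of the shared arrays for siAPC and in 6 of 6 for sibcat. Noise of single shared arrays is therefore excluded as the whole cause of this excess. A trait common to all 4 arrays of a single depletion stays in both parts of each division. The divisions therefore cannot test such a trait. The excess does not by itself mark reversal, since genes raised at both steps exceeded independent lists too. With the sibcat arrays divided, 981 to 1136 genes rose at both steps, against at most 606 for independent lists. Those raised and then lowered were fewer, at 771 to 832. Across genes, the covariance of the steps stayed negative with divided arrays (median -0.076 for siAPC and -0.038 for sibcat). A deeper beta-catenin knockdown came with TAZ siRNA in the sibcat background (CTNNB1 changed by -1.41 ± 0.05, SE). It would push sibcat-raised genes further up if they followed its depth, and a response that turns back with depth cannot be told apart from the effect of TAZ siRNA, since both changed in the same arrays. Loss of TAZ activity at TEAD targets is a candidate explanation, left open because no group received TAZ siRNA alone. YAP1 was also lower with TAZ siRNA, at 9.62 ± 0.07 in siAPC/siTAZ against 10.36 ± 0.06 in siAPC cells (log2 signal, SD, n = 4). In the sibcat background it stood at 10.14 ± 0.05 in sibcat/siTAZ against 10.505 ± 0.05 in sibcat cells. A part of YAP1 in the fall of these targets therefore cannot be told apart from that of TAZ.

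No other split or regrouping of the arrays gave as many genes as the real one, which is the most that 35 splits or 100 regroupings can show. Splits that mix widely different groups raise the spread within them, so few calls follow whatever made the groups differ. The test therefore cannot tell an siRNA effect from any other difference shared by the 4 arrays of a group. Among the 35 splits of 8 arrays, only 1, the real one, gave as many genes for each of the 7 comparisons of groups of 4 and 4. The real counts and the highest of the other splits were 7913 and 1 for siAPC against control, 7344 and 0 for sibcat against control, 8607 and 1 for TAZ siRNA in siAPC, 6264 and 4 for TAZ siRNA in sibcat, 9338 and 1 for siAPC/siTAZ against control, 8887 and 1 for sibcat/siTAZ against control, and 6690 and 0 for siAPC against sibcat. Among 100 regroupings, only 1, the real one, gave as many genes raised by siAPC and lowered (1891, highest other 0), raised by sibcat and lowered (1010, highest other 0), changed the same way by siAPC and sibcat (4414, highest other 0) and changed the same way by TAZ siRNA (4086, highest other 1). The same held for the difference between backgrounds, but less widely (5480, highest other 5012), since regroupings of these 16 arrays also set the groups' own differences against each other.

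The effect of added TAZ siRNA differed between backgrounds by the limma test of the difference itself for 10 of the 27 lists tested and for 5480 of 19775 genes (27.7%). Among the 44 named genes it differed for 36, but 10 of these were named for this difference and the others for large effects, so that share says nothing about other genes (26 of the 34 others differed). The list means (log2, siAPC minus sibcat background) were 0.69 for beta-catenin/TCF targets (17 of 26 genes higher), 0.35 for p53 targets, -0.30 for cholesterol biosynthesis (adjusted p = 0.00042), -0.37 for hypoxia and glycolysis (adjusted p = 2.4e-06), -0.71 for S phase, -0.82 for interferon response and -0.90 for mitosis (28 of 28 lower). Another 3 were lost with an estimated correlation: fibroblast markers (0.25, adjusted p = 0.161), mesenchymal genes (0.23, adjusted p = 0.0847) and TGF-beta/SMAD targets (0.28, adjusted p = 0.111).

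Among single genes, TAZ siRNA had the higher value in the siAPC background for BMP4 (difference 3.23, log2), ARL14 (3.08), OLR1 (3.04), IL33 (2.90), DKK2 (2.75), RGCC (1.93), CTNNB1 (1.69), FZD10 (1.63), EDIL3 (1.60), TNFSF10 (1.38), COL3A1 (1.17), CCN1 (1.04), FABP4 (1.02), MMP1 (0.98), COL1A1 (0.85), AXIN2 (0.53) and SULT1E1 (0.42). It had the lower value for PRR16 (-3.38), TIMP2 (-3.23), SDC2 (-2.73), SRGN (-2.71), DEK (-2.36), AOX1 (-2.05), OXTR (-1.98), TNFAIP6 (-1.47), F2RL2 (-1.23), PI15 (-1.04), APC (-0.67), ENPP2 (-0.53) and WWTR1 (-0.45). For another 6 genes the value was lower too, but their signal was low in both groups with TAZ siRNA: ZNF385B (-0.83), ITGB2 (-0.78), LYPD6 (-0.71), PSG9 (-0.57), SLC4A4 (-0.54) and ANKRD1 (-0.48). ANKRD1 ended at 3.09 and 3.02 from 8.73 in siAPC and 8.18 in sibcat cells, so its difference restates the starting level, and none of the 6 shows a different effect of TAZ siRNA by itself. DKK2 (2.52 and 2.68) and IL33 (2.99 and 3.10) had low signals in both sibcat and sibcat/siTAZ cells. An effect of TAZ siRNA on these genes could be hidden there, and the sizes of their differences are uncertain.

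Single arrays set apart from the other 3 of their group were sought for the named top genes, reporters and targets and for the list means, by the gap to the nearest array divided by the group's range. This ratio carries no size, so a tight group can stand out: the SD of ADAMTS1 in siAPC cells was only 0.01 (log2). Chance flags about 1 in 20 groups: 23 of 335 sets of gene and group stood out where chance gives about 17, and 12 of 135 sets of list and group where it gives about 7. The gene ratios were 1 for ADAMTS1 in siAPC B (10.61, the other 3 equal), 0.963 for LYPD6B in siAPC/siTAZ D, 0.946 for PTPRZ1 in sibcat B, 0.933 for CEACAM6 in sibcat A, 0.923 for CCN1 in sibcat/siTAZ A, 0.914 for OLR1 in control B, 0.912 for SLC6A14 in siAPC/siTAZ D, 0.909 for PRR16 in control D, 0.900 for BMP4 in siAPC/siTAZ A, 0.897 for SLC4A4 in siAPC C, 0.875 for ANKRD1 in siAPC/siTAZ A, 0.864 for FABP4 in control A, 0.861 for PI15 in control A, 0.857 for KRT13 in siAPC B, 0.842 for ITGB2 in siAPC/siTAZ A and for SERPINA3 in control C, 0.840 for PTGS1 in sibcat D and 0.839 for FZD10 in sibcat D. The ratio was 0.833 for AXIN2 in siAPC D, GABRP in siAPC/siTAZ C, ITGB2 in siAPC D, SERPINA3 in siAPC/siTAZ D and TDO2 in siAPC/siTAZ A.

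The list ratios were 0.960 for endothelial markers in control D, 0.951 for fibroblast markers in control D, 0.944 for interferon response in sibcat C, 0.927 for mesenchymal genes in control C, 0.892 for endothelial markers in siAPC/siTAZ C, 0.891 for TGF-beta/SMAD targets in sibcat D, 0.882 for S phase in sibcat/siTAZ A, 0.859 for leukocyte markers in sibcat/siTAZ A, 0.858 for extracellular matrix in siAPC/siTAZ D, 0.857 for TGF-beta/SMAD targets in siAPC/siTAZ C, 0.833 for luminal markers in siAPC C and 0.831 for Wnt receptors in sibcat/siTAZ A.

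Probe sets without a single gene symbol, 13522 in number, also changed at least 2-fold against their comparison group: 159 after siAPC (78 higher), 75 after sibcat (21 higher), 260 with TAZ siRNA in siAPC (175 higher) and 74 with TAZ siRNA in sibcat (30 higher).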

How the results depend on the processing

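All alternatives in this part were chosen before any result was seen. Targets, reporters and other named genes gave 543 results, none of which reversed under any alternative, and none of 108 list results reversed. Of 15647 comparisons of a named gene with an alternative, 75 lost and 34 gained a call, and 47 of the losses came from leaving out 1 array. APC lay between -0.90 and -0.86 in siAPC, CTNNB1 between -1.35 and -1.31 in sibcat, and WWTR1 between -2.68 and -2.64 and between -2.24 and -2.19 with TAZ siRNA in siAPC and sibcat when arrays were left out. The fall of APC with added TAZ siRNA lost its call with the mean of all probe sets (-0.10, adjusted p = 0.171), as did AXIN2 with TAZ siRNA in sibcat (0.11, adjusted p = 0.181), and the cause was not tested. No scaling moved the share of higher calls by 10 points, the widest move being from 43.9% to 50.7% in the difference between backgrounds. Low signals limit what can be seen: control signals such as those of ABCA8 (2.84), ANKRD1 (3.08), OLR1 (3.68) and LYPD6 (3.69) lie well below the array medians, where background signal can compress a fold change, and so do the end points of falls such as SCGB1A1 (2.99 in siAPC).

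With every probe set tested, more tests gave more calls: 16494 for siAPC, 14212 for sibcat, 19396 and 12345 for TAZ siRNA in siAPC and sibcat, 21134 and 19132 for siAPC/siTAZ and sibcat/siTAZ against control, 10212 for the difference between backgrounds, 13610 for siAPC against sibcat, 3450 and 1781 raised by siAPC or sibcat and then lowered, 8256 changed the same way by siAPC and sibcat, and 8127 changed the same way by TAZ siRNA. With a fold change of at least 1.5, a stricter rule by construction, the counts in that order were 1800, 1335, 2272, 1194, 2800 and 2203, then 343 and 248 raised and then lowered, 838 the same way by siAPC and sibcat and 846 the same way by TAZ siRNA. With arrays left out, counts lay between 7404 and 8062 for siAPC, 6889 and 7362 for sibcat, 8130 and 8747 and 5797 and 6272 for TAZ siRNA, 1731 and 1948 and 927 and 1033 for genes raised and then lowered, and 3847 and 4098 for shared TAZ effects. With the replicate letter as a block, between 97.1% and 98.4% of the calls were kept.

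Of the 54 list calls, 14 were lost and 12 others gained under some alternative. Calls lost with an estimated correlation, which was above the preset 0.01 in each of these lists, had adjusted p = 0.119 (basal), 0.154 (interferon) and 0.203 (p53) after siAPC, 0.0964 (mesenchymal) and 0.111 (siRNA targets) after sibcat, 0.0952 (TGF-beta/SMAD and p53), 0.114 (fibroblast), 0.210 (luminal) and 0.256 (extracellular matrix) with TAZ siRNA in siAPC, and 0.126 (siRNA targets) with TAZ siRNA in sibcat. With every probe set tested, beta-catenin/TCF targets after siAPC (0.149) and extracellular matrix with TAZ siRNA in siAPC (0.445) lost their calls. Calls were gained by luminal markers (0.00030) and Hippo components (0.00689) after sibcat, siRNA targets after siAPC (0.00191), Wnt receptors with TAZ siRNA in siAPC (0.0123), and fibroblast (0.00034), adherens junction (0.00118) and actin genes (0.0270) with TAZ siRNA in sibcat. With the stricter filter (50% of genes dropped), cholesterol (0.168) and p53 (0.176) after siAPC, cholesterol and mesenchymal genes after sibcat (0.126 each) and extracellular matrix with TAZ siRNA in siAPC (0.236) lost their calls, and fibroblast markers with TAZ siRNA in sibcat gained one (0.0245). With the milder filter on low signals, cholesterol (0.0502) and p53 (0.0801) after siAPC and extracellular matrix with TAZ siRNA in siAPC (0.113) lost theirs.

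With the mean of all probe sets, adherens junction (0.0247), actin (0.0309) and extracellular matrix genes (0.0372) gained calls with TAZ siRNA in sibcat. With quantile normalization, mitosis after siAPC (0.0473) and adherens junction after sibcat (0.0496) gained calls and p53 after siAPC lost its call (0.0881). Extracellular matrix with TAZ siRNA in sibcat (adjusted p = 0.0502) also passed with array weights (0.0342), the replicate block (0.0497) and a trended and robust variance (0.0351). The cause was not tested for the calls changed by the filters, the probe set choices, the normalization or the variance settings.

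Leaving out 1 array changed a call in 7 lists, with these lowest and highest adjusted p. After siAPC these were leukocyte markers (0.0479 to 0.0873, passing without siAPC A), p53 targets (0.0283 to 0.0573, missing without control A) and siRNA targets (0.0464 to 0.0941, passing without control D). After sibcat these were mesenchymal genes (0.0238 to 0.0627, missing without sibcat D). With TAZ siRNA in sibcat these were actin genes (0.0484 to 0.111, passing without sibcat B), TGF-beta/SMAD targets (0.0233 to 0.118, passing without sibcat D) and extracellular matrix (0.0131 to 0.0947), which passed without control B or C, any 1 siAPC/siTAZ array, or B or D of sibcat or sibcat/siTAZ. Over all alternatives, the adjusted p of beta-catenin/TCF targets after siAPC lay between 0.00013 and 0.149, of interferon genes after siAPC between 6.0e-05 and 0.154, of TGF-beta/SMAD targets with TAZ siRNA in siAPC between 2.4e-05 and 0.0952 and of mitosis after siAPC between 0.0473 and 0.409.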

Other observations

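Several genes lost most of their signal in siAPC/siTAZ cells alone. TIMP2, an inhibitor of matrix metalloproteinases, stood at 7.81 ± 0.05 (log2, SD, n = 4) in siAPC/siTAZ cells against 10.87 ± 0.02 in the control, 11.16 ± 0.05 in siAPC, 11.39 ± 0.05 in sibcat and 11.27 ± 0.05 in sibcat/siTAZ cells. The chromatin gene DEK stood at 8.99 ± 0.04 there and between 11.58 and 11.90 in the other groups. The proteoglycan gene SDC2 stood at 5.84 ± 0.06 and otherwise between 7.38 and 8.82. The gap junction gene GJA1 was high only with APC siRNA. It stood at 9.79 in siAPC and 10.69 in siAPC/siTAZ cells against 6.40 in the control, 5.67 in sibcat and 6.11 in sibcat/siTAZ cells, whereas the tryptophan dioxygenase TDO2 stood at 7.29 in siAPC and 9.10 in siAPC/siTAZ cells, 2.95 in the control, 3.47 in sibcat and, without APC siRNA, 5.49 in sibcat/siTAZ cells. SCGB1A1 stood at 7.86 ± 0.04 in the control and between 2.99 and 3.31 in every other group.

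GAPDH, the other RNA quality measure, had a 3' minus 5' signal between 0.09 and 0.18 in the group means. It differed by 0.03 between siAPC and control (two-sided exact permutation p = 0.0286, adjusted p = 0.114), by 0.03 between sibcat and control (exact p = 0.143, adjusted p = 0.143) and by 0.03 between siAPC/siTAZ and siAPC (exact p = 0.0857, adjusted p = 0.114).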
